A study of Caenorhabditis elegans with 10 samples.

How the data were processed

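Total RNA from whole Caenorhabditis elegans was hybridised by the authors to 10 one-colour Affymetrix C. elegans arrays after biotin labelling with a one-cycle 3' IVT protocol, per the labels. The arrays covered larvae of stage L3 (2 wild-type and 2 nep-1 mutant arrays) and adults (3 wild-type and 3 nep-1 mutant arrays). The titles call the replicates biological, so the p-values measure variation between separately prepared samples as far as those titles state it. The deposited expression values are log2 values made by the authors with RMA, per the submitters' processing notes, which give no version. The deposited comparison tables also hold, per the file headers, a scaled signal and a detection call (present, marginal or absent) for each array, and a log2 ratio and a change call for each pair of a mutant and a wild-type array. The authors' deposited lists of changed transcripts hold probe sets with an increased or decreased call in a minimum number of those pairs, 3 or 4 of 4 in larvae and 7, 8 or 9 of 9 in adults. A recount matched them with a filter on present calls, in every pair for increases and on every wild-type array of the stage for decreases. Another 40 columns were not used here, of which 16 repeated mutant signals or detection calls that matched the used columns and 24 held detection p-values or other entries.

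The log2 values were not normalised again for the comparisons reported. Of 22625 probe sets, 77 controls were left out and 22548 were tested without a filter. Detection calls were present for 11184 to 13939 probe sets per array. For arrays, it is their number that limits the precision. limma 3.58.1 in R 4.3.3 fitted a mean to each of the 4 groups over all 10 arrays, with 6 residual degrees of freedom, 2.57 prior degrees of freedom and a median residual SD of 0.35 on the log2 scale. The contrasts were mutant minus wild-type in larvae, mutant minus wild-type in adults, the difference between those changes (adult minus larval), and the mean of the adult groups minus the mean of the larval groups. Two-sided p-values were adjusted by Benjamini-Hochberg over all tested probe sets in each contrast, with a threshold of 0.05. The comparisons, tests, gene lists and most of the alternatives were chosen before the data were examined. Tables were read with Python 3.11.15.

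The files pair probe sets with gene numbers only in the authors' lists of changed transcripts. Those 196 probe sets gave 152 with a single gene in a RefSeq gene table of assembly WBcel235, which named 145 genes. A further 4 probe sets had several genes, 37 had no gene number, and 3 had a number that the table lacks. Each gene was represented by its probe set with the highest mean over the 10 arrays. The rule named nep-1 and other neprilysin genes, and the 12 largest rises and 12 largest falls past the threshold per genotype contrast. Where fewer than 10 genes passed, it named instead the 8 largest rises and 8 largest falls among genes above the median level whose mutant and wild-type arrays did not overlap. It also named the 8 smallest p-values past the threshold of the interaction, the 6 largest stage rises and 6 largest falls past it, up to 4 members of each described list, the 5 largest changes of each authors' list, and up to 10 genes past the threshold in both stages, of which there were 0 in limma. No coordinates are given because the sequences of the probe sets were not analysed here. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with a minimum of 3 named genes. Of 36 lists, 13 had a named member, 6 were tested and 23 had none. Each named member had been chosen by the study on these same arrays, nearly all on the larval ones. A list's direction in the stage of that choice is therefore not independent evidence. The nep-1 level was also compared by an exact two-sided permutation test within stages, which did not keep the array pairs.

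Alternatives were quantile normalisation, centring each array on its median, the upper 60% of probe sets by mean level, probe sets present on at least 2 arrays of the stage, an intensity trend with robust estimation, array weights, an absolute log2 change of at least 1, each stage alone, the scaled signals (log2 after adding 16), a camera correlation estimated per list, 1 probe set per gene, the fry test, leaving out each array in turn, and blocks. The replicate numbers of the titles, the naming styles of the descriptions, and the pairs of letters or bare names in the descriptions served as blocks. The last of these, its use as a random block (duplicateCorrelation, correlation 0.528), the fits without the adult pair with bare names, and an estimated camera correlation in these fits and with the naming styles as a block were added after the data had been seen. Title numbers did not pair the adult arrays. Deviations from the group mean of mutant and wild-type arrays with the same number correlated across probe sets at −0.583, −0.181 and −0.693, against 0.657, 0.665 and 0.653 for arrays paired by letter or bare name. In larvae both schemes give the same pairs, at 0.566. Genes are not independent replicates in these correlations.

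The fit was tested on simulated data with 22548 probe sets, of which 200 were changed. The simulated arrays varied independently, unlike the correlated array pairs here, so the rates below hold only for independent arrays. Of changes of 1 on the log2 scale, 0% were recovered in the larval, adult and interaction contrasts and 36.0% in the stage contrast. Of changes of 2, the larval contrast recovered 56.0%, the adult contrast 65.5%, the interaction 34.5% and the stage contrast 78.0%. Of changes of 4, they recovered 89.5%, 94.0%, 79.0% and 96.5%. False calls numbered 0 to 16 per simulation.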

Results

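Transcripts were measured on 10 arrays of whole worms, 1 array per RNA sample, from wild-type Caenorhabditis elegans and from a nep-1 mutant whose allele came from EMS mutagenesis. nep-1 encodes a neprilysin, a zinc metallopeptidase that cleaves peptides at the cell surface. Larvae of stage L3 gave 2 wild-type and 2 mutant arrays, and adults gave 3 and 3. Present calls ranged from 11184 probe sets (49.6%) on larval mutant 1 to 13939 (61.8%) on adult mutant 1, and array medians ranged from 5.82 to 6.09 on the log2 scale. The descriptions of the arrays pair a mutant with a wild-type array by a naming style or a letter. The larval pairs were mutant 1 with wild-type 1 and mutant 2 with wild-type 2. The adult pairs were mutant 2 with wild-type 1 (letter A), mutant 3 with wild-type 2 (letter B) and mutant 1 with wild-type 3 (bare names). Across probe sets, which are not independent replicates, correlations within these pairs were 0.992, 0.974, 0.984, 0.992 and 0.955. In the last pair adult wild-type 3 was about as close to adult mutants 2 and 3, at 0.956 each. The adult arrays with bare names stood apart, with a mean correlation to the larval arrays of 0.903 for wild-type 3 and 0.891 for mutant 1 against 0.830 to 0.837 for the other adult arrays. The spike-in control bioB also differed between larval pairs, at log2 5.52 and 5.32 in the first pair and 7.67 and 7.50 in the other.

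nep-1 itself (probe set 188537_s_at) was lower in the mutant at both stages. In larvae it measured 8.68 ± 0.69 (SD, n = 2) in wild-type and 5.03 ± 0.25 (SD, n = 2) in the mutant on the log2 scale, a difference of −3.65 ± 0.45 (SE). It was called absent on both larval mutant arrays, so background limits this difference. The wild-type mean was 12.6-fold above the mutant mean, or 8.96-fold at the lowest when leaving out an array. These are estimates from few arrays, not lower limits. In adults it measured 6.73 ± 0.66 (SD, n = 3) in wild-type and 5.19 ± 0.20 (SD, n = 3) in the mutant, a difference of −1.54 ± 0.37 (SE). The probe set was called present on 2 adult mutant arrays and marginal on 1, but its level there lay near that of the absent calls in larvae, so background limits this difference too. The mutant was lower in 5 of 5 array pairs, by differences of −2.99 and −4.31 in larvae and −0.92, −1.43 and −2.27 in adults. In the scaled signals the adult genotypes overlapped, with 93.6 on mutant 1 against 68.5 on wild-type 1, which are not a pair. The authors' calls placed nep-1 on their adult list for at least 7 of 9 pairs, but not for 8. An exact permutation test with labels permuted within stages gave a two-sided p of 0.0167, the smallest that its 120 arrangements can give. It shuffled arrays freely within a stage, although the arrays of a pair deviated together. Keeping the pairs would leave fewer arrangements and a larger smallest p, so a test that keeps them could not reach this value. The free shuffle is therefore not exact for these paired arrays. Larvae alone cannot go below an exact p of 0.333, nor adults alone below 0.1. Across all probe sets, nep-1 ranked 1 by limma p in each stage, with adjusted p = 0.603 in larvae and adjusted p = 1 in adults. The position of the lesion relative to the probes was not given in the labels, so these values check the genotype labels only as far as the allele lowers the transcript.

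**Figure D1:**
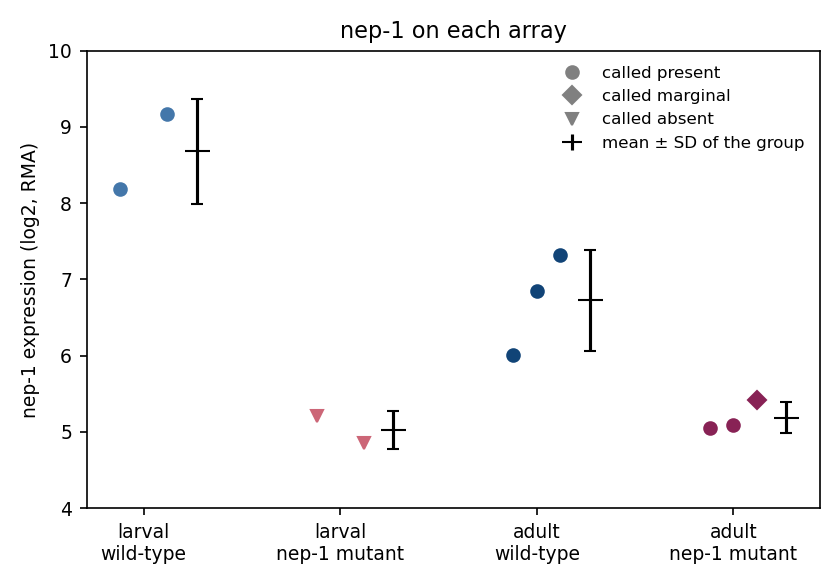
Log2 level of nep-1 on each of the 10 arrays by stage and genotype, with each group's mean and SD. Both larval mutant arrays, with a mean of 5.03, lie below both larval wild-type arrays, with a mean of 8.68, and the adult means are 6.73 in wild-type and 5.19 in the mutant.

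The larval comparison asked how the L3 transcriptome differs between the nep-1 mutant and wild-type. Cuticle collagens, which build the worm's exoskeleton, fell in the mutant as a list, with a median log2 change of −1.27 over 13 named genes, 12 of them lower. Hedgehog-related and patched-related genes of the epidermis fell by a median of 1.05 over 5 genes, all 5 lower. UDP-glucuronosyltransferases, which conjugate foreign compounds, fell by a median of 1.11 over 3 genes, all 3 lower. Genes of fatty acid and lipid metabolism fell by a median of 0.81 over 10 genes, 8 of them lower. These were the 4 of 6 tested lists past the threshold of limma's camera, with adjusted p = 0.00134 for the collagens, adjusted p = 0.00134 for the hedgehog-related list, adjusted p = 4.07e-05 for the glucuronosyltransferases and adjusted p = 0.00134 for the lipid list. With an estimated correlation camera gave adjusted p = 0.348, adjusted p = 0.216, adjusted p = 0.030 and adjusted p = 0.160 in that order, so that only the glucuronosyltransferases kept their call, which they lost with letter pairs as a block and an estimated correlation (adjusted p = 0.0766). Over 22 other fits the camera adjusted p ranged from 1.35e-06 to 0.908 for the collagens, from 3.79e-07 to 0.757 for the hedgehog-related list, from 3.79e-07 to 0.181 for the glucuronosyltransferases and from 4.08e-05 to 0.503 for the lipid list. The members could be named only because the study had called them changed on these same arrays, so neither the counts nor the list tests are independent evidence of direction, and unlisted members on the array could not be counted.

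Among the collagens, col-54 had a larval log2 difference of −1.74 ± 1.05 (SE), col-77 −1.55 ± 1.15, col-156 −1.49 ± 1.16 and col-111 −1.30 ± 0.79, each from 2 arrays per genotype. Each SE comes from a fit that took no account of the array pairs, so it is not the spread of differences within pairs. It also rests on a spread shared by all 10 arrays, adults included, and is not the larval replicate spread. For acox-1.2, listed below, SDs were 0.008 and 0.12 in larvae against 0.76 and 1.23 in adults. For col-54 they were 2.34 and 0.67 against 1.28 and 0.22 (wild-type, then mutant). Leaving out each array in turn moved them between −3.39 and −0.08 for col-54, −3.15 and 0.042 for col-77, −2.81 and −0.16 for col-156 and −2.27 and −0.33 for col-111. col-142 went the other way, at 1.28 ± 1.25. 0 of the 13 passed when adjusted over the list alone, and 0 when adjusted over all probe sets. In the hedgehog-related and patched-related list, ptr-6 had a difference of −1.39 ± 0.91, grl-5 −1.07 ± 1.22, ptr-18 −1.05 ± 1.28 and grd-5 −1.02 ± 0.85, and 0 of 5 passed when adjusted over the list alone. Genes of the abu and pqn families, many of them part of the pharyngeal cuticle, had a median of −0.95 over 4 genes, all 4 lower, and did not pass as a list in the fit without blocks (camera adjusted p = 0.0641, or adjusted p = 0.398 with an estimated correlation). The list passed in 11 of 22 alternatives, among them naming styles as a block (adjusted p = 0.000237) and letter pairs as a block (adjusted p = 1.89e-05), in a range of 1.54e-05 to 0.908. With an estimated correlation those blocks gave adjusted p = 0.196 and adjusted p = 0.179. In this list abu-14 had a difference of −1.35 ± 1.64, pqn-13 −1.20 ± 1.07 and abu-13 −0.66 ± 1.31, and 0 of 4 passed when adjusted over the list alone. Each of these cuticle lists was also higher in replicate 2 than in replicate 1 of the same genotype. For the collagens the median of that difference was 1.45 in wild-type and 1.29 in the mutant, for the hedgehog-related list 1.30 and 1.60, and for abu and pqn 1.25 and 1.003. Within array pairs the medians of mutant minus wild-type were −0.87 and −1.09 for the collagens, −1.25 and −0.84 for the hedgehog-related list and −0.83 and −1.22 for abu and pqn. The log2 difference between 3' and 5' ends of control transcripts, a sign of RNA quality, was 1.18 and 1.12 on the larval mutant arrays and 1.06 and 0.93 on the larval wild-type arrays.

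Among the glucuronosyltransferases, ugt-44 had a difference of −1.58 ± 0.45, ugt-63 −1.11 ± 0.63 and ugt-6 −0.96 ± 0.72, and 1 of 3, ugt-44, passed when adjusted over the list alone. All 3 had been called decreased by the study on these larval arrays, so that adjustment leaves out the screen that chose them. When adjusted over all probe sets, 0 passed. The lipid list held lips-3, a lipase, at −1.77 ± 1.25, acox-1.2, an acyl-CoA oxidase, at −0.93 ± 0.72, elo-3, a fatty acid elongase, at −0.85 ± 0.56, and lbp-3, a lipid-binding protein, at −0.76 ± 0.25. Its exceptions were fat-7, a stearoyl-CoA desaturase, at 0.59 and fasn-1, the fatty acid synthase, at 0.68, and 0 of 10 passed when adjusted over the list alone. Pair medians were −1.13 and −1.09 for the glucuronosyltransferases and −0.87 and −0.64 for the lipid list, while replicate 2 exceeded replicate 1 by medians of 0.95 in wild-type and 1.01 in the mutant for the former and by 0.44 and 1.02 for the latter. Glutathione S-transferases did not pass as a list (camera adjusted p = 0.0876, or adjusted p = 0.216 with an estimated correlation), but did in 8 of 22 alternatives, among them letter pairs as a block (adjusted p = 0.0467, in a range of 0.00446 to 0.770, or adjusted p = 0.242 with an estimated correlation). Of its 4 genes, gst-10 measured −0.81 ± 0.82, gst-13 −0.75 ± 0.26 and gst-6 −0.52 ± 0.68, gst-20 measured 0.50 ± 0.34, and 0 of 4 passed when adjusted over the list alone. Lists with a single named gene were not tested, and the larval differences were −0.68 for the lysozyme lys-2, −0.92 for the astacin nas-6, −0.32 for mlt-8 of the moulting list, −0.73 for the cytochrome P450 cyp-35C1, 0.19 for the neuropeptide-like nlp-8 and −0.65 for rol-6 of the adult cuticle list. The count of 4 called lists became 0 without larval mutant 1, 1 (the glucuronosyltransferases) without larval wild-type 2 and 0 with fry. Leaving out each array in turn moved the list medians over probe sets between −2.03 and −0.15 for the collagens, −1.91 and −0.24 for the hedgehog-related list, −1.80 and −1.08 for the glucuronosyltransferases and −1.08 and −0.21 for the lipid list.

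**Figure D2:**
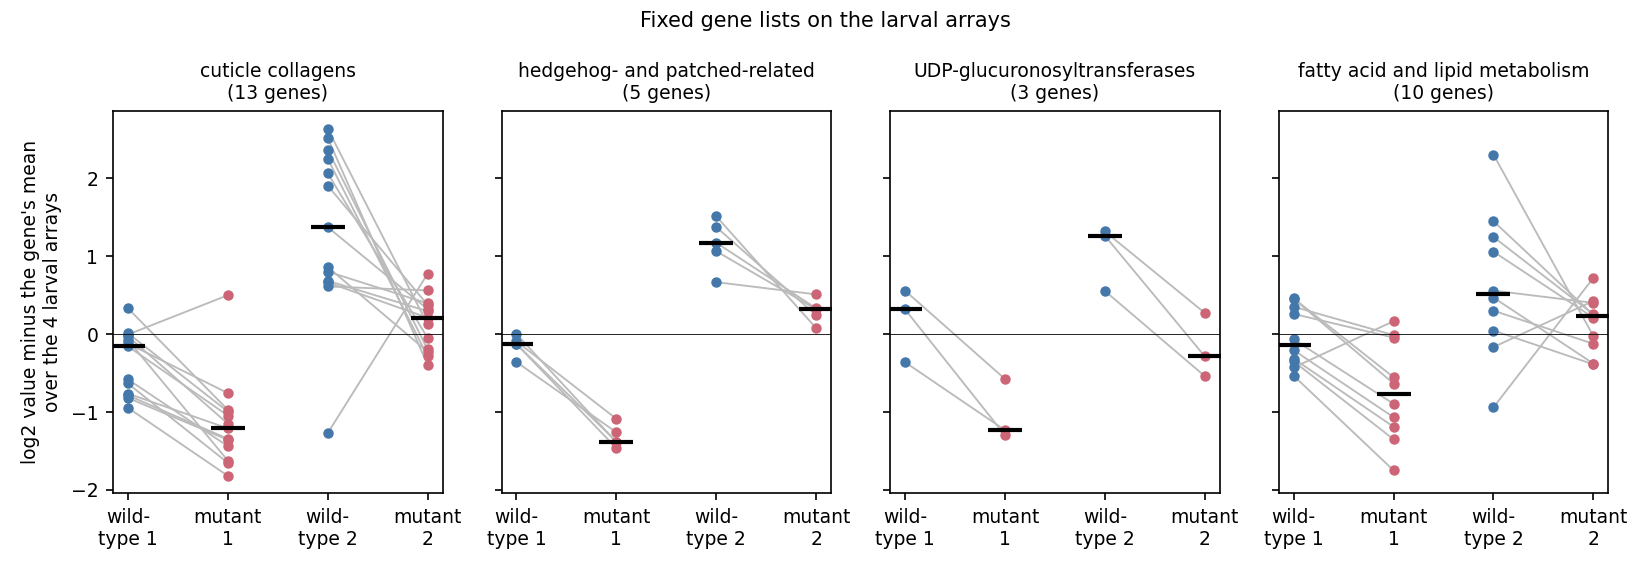
Log2 level of each named member of the 4 called gene lists on the 4 larval arrays, as the difference from the gene's mean, with lines joining the arrays of a pair and bars at the list medians. The median mutant change was −1.27 for the 13 collagens and −1.11 for the 3 glucuronosyltransferases, and the collagens were also higher in replicate 2 than in replicate 1, by a median of 1.45 in wild-type.

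For single genes, 0 of 22548 probe sets passed the limma threshold in larvae, and 150 had an unadjusted p under 0.05 where 1127 would by chance if arrays were independent. Wild-type and mutant arrays did not overlap for 1719 probe sets higher and 2845 lower in the mutant, together 20.2%, where chance gives 33.3% for independent arrays. Deviations from the group means correlated at 0.566 within the larval pairs and 0.653 to 0.665 within the adult pairs, so these chance values, and those given below for adults and for both stages, are too high for these arrays. Besides nep-1, the lowest named genes without overlap were the lipocalin-related lpr-7 at −1.92 ± 0.73, ZK180.6 at −1.86 ± 1.28, F33A8.7 at −1.70 ± 1.33, W02F12.2 at −1.67 ± 0.58, ugt-44 at −1.58 ± 0.45, F46C8.8 at −1.44 ± 1.02 and srlf-19 at −1.41 ± 1.11. The highest were col-142 at 1.28, atf-8 of the bZIP family at 0.98 ± 0.96, the muscle protein gene ketn-1 at 0.83 ± 0.67, the tubulin tbb-6 at 0.71 ± 0.39, henn-1 at 0.69 ± 0.81, F53A9.8 at 0.66 ± 0.86, scl-5 at 0.66 ± 0.58 and fat-7 at 0.59 ± 0.96. With naming styles as a block the limma count was again 0, with 617 at an unadjusted p under 0.05. The authors' lists, recounted from the deposited calls with the filter on present calls, held 44 probe sets increased and 142 decreased in at least 3 of 4 array pairs. Before that filter the counts were 46 and 148. Of the decreased probe sets, 12 were decreased in 4 of 4. Of the 142, 135 were called decreased in the first larval pair and 142 in the other, but 27 for larval mutant 2 against larval wild-type 1. Their medians within pairs were −0.87 and −1.09. The largest named differences on the stricter list were nep-1, lpr-7, W02F12.2, ugt-44 and oac-29, the last at −1.37 ± 0.54, and on the wider list also ZK180.6, pud-2.1 at −1.79 ± 1.27 and lips-3. On the increased list C15A11.7 measured 1.04 ± 0.80 and Y41G9A.5 0.85 ± 0.77. Of 43 larval differences of named genes and single probe sets, leaving out each array in turn moved 34 by over 1.5 times and changed the sign of 1, col-77. Ranges were −3.53 to −0.06 for pud-2.1, −3.19 to −0.35 for lips-3, −2.95 to −0.45 for F33A8.7, −2.94 to −0.89 for lpr-7, −2.88 to −0.83 for ZK180.6, −2.34 to −1.005 for W02F12.2, −2.09 to −1.08 for ugt-44, −1.78 to −0.96 for oac-29, 0.26 to 1.82 for C15A11.7, 0.23 to 1.73 for atf-8 and 0.03 to 1.68 for Y41G9A.5.

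The adult comparison asked the same question in grown worms. Besides nep-1, cyp-35C1, a cytochrome P450, had a log2 difference of −0.90 ± 0.36 (SE, 3 arrays per genotype), and gda-1 had a difference of 0.84 ± 0.26. These were the named genes above the median level whose arrays did not overlap. From the authors' adult lists, T04A11.4 measured 1.25 ± 0.56 and F01D5.5 1.06 ± 0.66, while Y51H7C.1 measured −1.36 ± 0.81, the acyl-CoA oxidase acox-1.2 −1.31 ± 0.59, Y48E1B.8 −1.27 ± 0.59 and the acyl-CoA dehydrogenase acdh-2 −1.26 ± 0.54. The largest of these negative differences came from the pair with bare names, where cyp-35C1 differed by −1.996, Y51H7C.1 by −3.95 and acdh-2 by −2.79, against −0.42, −0.57 and −0.40 in the letter A pair and −0.28, 0.44 and −0.59 in the letter B pair. Of 12 adult differences of named genes and single probe sets, nep-1 included, leaving out each array in turn moved 7 by over 1.5 times and changed the sign of 0. Ranges were −1.17 to −0.43 for cyp-35C1, −1.945 to −0.25 for Y51H7C.1, −1.74 to −0.55 for acdh-2, −1.815 to −0.62 for acox-1.2, −1.83 to −0.67 for Y48E1B.8, 0.49 to 1.81 for F01D5.5, 0.83 to 1.745 for T04A11.4 and 0.71 to 1.05 for gda-1. In limma 0 of 22548 probe sets passed, with 69 at an unadjusted p under 0.05. Arrays did not overlap for 343 probe sets higher and 440 lower in the mutant, 3.47% against 10% by chance for independent arrays. With naming styles as a block the limma count was 0 with 540 at an unadjusted p under 0.05, and with the letter pairs as a block it was 0 with 623. The authors' lists held 4 probe sets increased in at least 7 of 9 pairs and 9 decreased, of which 2 were decreased in at least 8 and 1 in all 9. The last was 176872_at, which has no gene number and measured −0.99 ± 0.49 (−1.375 to −0.36 when leaving out each array), and the increased list held 194060_s_at at 0.87 ± 0.32 (0.66 to 1.19).

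No gene list passed in adults. limma's camera called 0 of 6, with 2 at an unadjusted p under 0.05, and an estimated correlation or fry also gave 0. Fatty acid and lipid genes had a median of −0.26 over 10 genes, 8 of them lower (adjusted p = 0.0936), and the glucuronosyltransferases −0.41 over 3 genes, all 3 lower (adjusted p = 0.144). The collagens had a median of −0.45 with 9 of 13 lower (adjusted p = 0.464), the hedgehog-related list −0.28 with 3 of 5 lower (adjusted p = 0.481), the glutathione S-transferases −0.02 with 2 of 4 lower (adjusted p = 0.481), and abu and pqn 0.17 with 4 of 4 higher (adjusted p = 0.477). In each of the 6 lists 0 genes passed when adjusted over the list alone. Their members had been chosen by the study on the larval arrays, except acdh-2, chosen on the adult arrays, and acox-1.2, chosen on both. Without the adult arrays with bare names, the collagens, the hedgehog-related list and the glutathione S-transferases changed sign, while the glucuronosyltransferases (−0.10) and the lipid list (−0.05) stayed lower and abu and pqn stayed higher. In that fit 2 lists passed at the preset correlation of 0.01, the collagens with a median of 0.65 (camera adjusted p = 1.71e-06, in a range of 1.71e-06 to 0.880 over the alternatives) and abu and pqn with 0.86 over probe sets (adjusted p = 0.000220, in a range of 2.95e-05 to 0.753). Estimated from that fit the correlations were 0.705 and 0.698, and 0 lists passed (adjusted p = 0.456 for each of these). With the letter pairs as a block, the glucuronosyltransferases and the lipid list, both lower, passed instead at the preset correlation (adjusted p = 0.0318 for each, in ranges of 0.0318 to 0.476 and 0.00333 to 0.792), but not at an estimated one (adjusted p = 0.430 and adjusted p = 0.639). Leaving out adult wild-type 1, 2 or 3 gave 2, 4 and 3 called lists, the last 3 all higher in the mutant. The arrays with bare names also had the largest 3' to 5' log2 differences of control transcripts among adults, at 1.16 and 1.32 against 0.82 to 0.96.

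**Figure D3:**
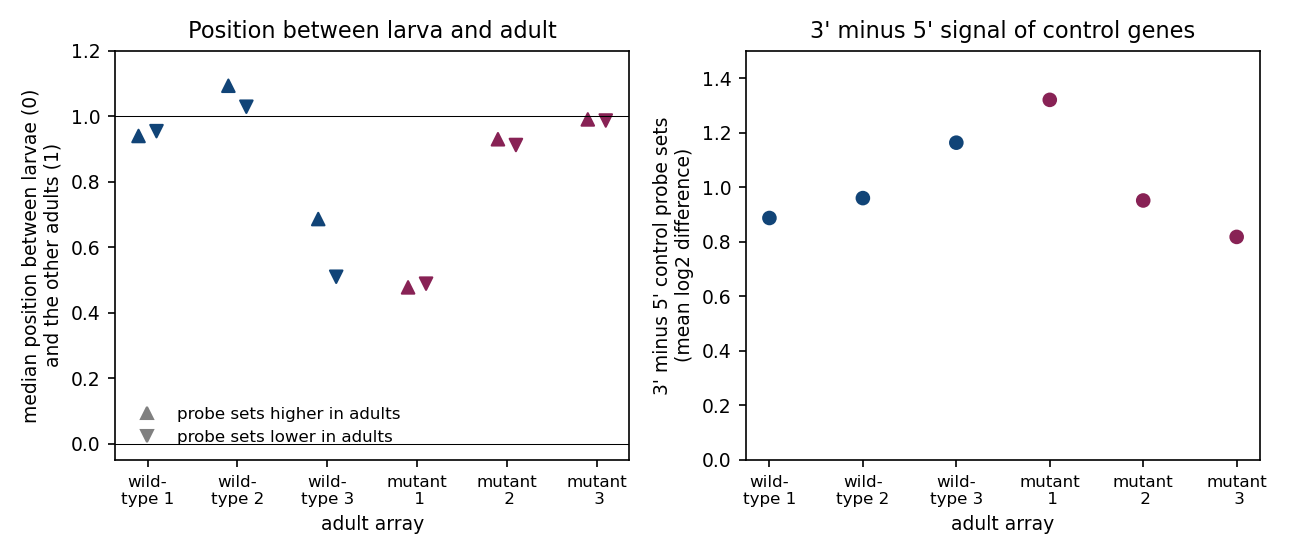
For each adult array, the median position of stage-changed probe sets between the larval mean (0) and the mean of the other adult arrays with letter names (1), and the mean log2 difference between 3' and 5' control probe sets. Wild-type 3 and mutant 1, the arrays with bare names, lie between 0.477 and 0.686 in position, below the 0.912 to 1.09 of the other adult arrays, and have the highest 3' to 5' differences, 1.16 and 1.32.

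The difference between the adult and the larval change was tested as an interaction. For nep-1 the interaction was 2.11 ± 0.58 (SE, limma unadjusted p = 0.00596, adjusted p = 1), which did not pass over all probe sets. nep-1 was called absent on both larval mutant arrays, and the adult mutant mean of 5.19 lay near their 5.03, so this value is limited by background and does not show that the genotype change differed between stages. The descriptions also carry different number codes for larval mutant 1 and for adult mutants 2 and 3, and a difference in strain was not separated from stage in any contrast across stages. In limma 0 of 22548 probe sets passed, with 92 at an unadjusted p under 0.05. Among probe sets without overlap in either stage, 72 moved the same way in larvae and adults, 30 higher and 42 lower, and 91 moved in opposite ways, where chance gives 376 of each kind for independent arrays, a comparison that the correlated pairs make void.

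The stage comparison set adults against larvae over both genotypes. Adults had higher vha-18, a subunit of the vacuolar proton pump, by a log2 difference of 3.24 ± 0.35 (SE, 6 adult and 4 larval arrays), rskn-1, a ribosomal S6 kinase, by 2.28 ± 0.16, acdh-2 by 2.69 ± 0.43, atgl-1, a triglyceride lipase, by 1.64 ± 0.22, Y51H7C.1 by 2.57 ± 0.64 and M01H9.3 by 1.18 ± 0.19. Y51H7C.1 was called absent on every larval array, so background limits its difference. Lower in adults were the cuticle collagens col-90 at −4.39 ± 1.07, rol-6 at −3.56 ± 0.62 and dpy-5 at −3.54 ± 1.11, with ZK1025.3 at −4.65 ± 1.12, F56D3.1 at −3.62 ± 0.62 and oac-29 at −3.50 ± 0.35. ZK1025.3 was called present on 1 of 3 adult wild-type and 1 of 3 adult mutant arrays. For rol-6 and oac-29 these counts were 1 and 2, and for F56D3.1 1 and 3. Background may limit these differences too, while col-90 and dpy-5 were called present on all adult arrays. The limma adjusted p-values ran from 4.81e-05 for rskn-1 to 0.0370 for dpy-5. Of the 13 named collagens 6 were called lower in adults and 0 higher, with a median of −1.88, as were 2 of 5 hedgehog-related and patched-related genes with a median of −2.28 and 2 of 4 abu and pqn genes with a median of −2.88. These genes had been listed by the study for their genotype calls, not for stage.

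Over all probe sets limma called 8033 of 22548 (35.6%) changed with stage, 4459 higher and 3574 lower in adults. The split depended on the scaling: 55.5% of the calls were higher in adults as deposited, 45% of 7333 after quantile normalisation and 47.4% of 8003 with each array centred on its median. Every pair of a mutant and a wild-type array held a single stage, so these pairs were also entered as a random block, which gave 5169 calls, 3320 higher and 1849 lower. In that fit ZK1025.3, dpy-5 and Y51H7C.1 lost their call. Without larval mutant 2, ZK1025.3, Y51H7C.1 and col-90 also lost it, with differences of −4.32, 2.50 and −4.07, and dpy-5 lost it without any single array other than those with bare names, at −3.78 to −2.94. Stage was not separated from the date or batch of an array pair, as the labels give neither. The differences of Y51H7C.1 are limited by background here too, as it was called absent on every larval array.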

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

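The test of the larval falls in adults, the fits without the adult arrays with bare names, the random block, the splits that keep pairs whole and the selection of larval falls within array pairs were chosen only after the results were seen.

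nep-1 was singled out by a limma test of the difference between its adult change (−1.54) and its larval change (−3.65), which was 2.11 ± 0.58 (SE, unadjusted p = 0.00596, adjusted p = 1 over all probe sets). Wild-type levels were 8.68 in larvae and 6.73 in adults, and mutant levels 5.03, where the probe set was called absent on both arrays, and 5.19. With mutant levels that near background, the value cannot show that the effect of the genotype differed between stages.

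The 142 probe sets that the authors list as decreased in mutant larvae had medians of −0.87 and −1.09 in the larval pairs. Whether mutant larvae were further along towards adulthood was not decided by the 4459 probe sets that rise from larva to adult, whose median larval change was −0.071 (quartiles −0.20 and 0.05, pairs −0.08 and −0.06), near the −0.08 and 0.01 of all probe sets in the same pairs. The same 142 probe sets differed between the larval wild-type arrays by a median of 1.27, and between the larval mutant arrays by 0.962. Replicate 2 was higher for 136 and 132 of them. The highest of 10000 random lists of equal mean level gave 0.462 and 0.539, but those lists were not chosen for changes on these arrays. The 142 were, by calls that can favour such differences, so the comparison is no independent evidence. Choosing 143 probe sets from the array pairs alone gave 1.265 and 0.958, but 135 of these were among the 142. For the 142, cultures that differed whatever their genotype, in moult timing for example, stayed possible. In adults the median of the 142 was −0.073 (limma's camera, adjusted p = 0.164, or p = 0.799 with an estimated correlation). Without the arrays with bare names it was 0.30, the other way (camera p = 1.73e-10 at the preset correlation of 0.01). The adult pairs gave 0.42, 0.27 and −0.94, so whether adults share a genotype effect cannot be told apart from differences between pairs. A genotype effect in larvae alone, or another mutant position within the moult cycle, stayed open, since with the naming pairs as a block limma called 0 larval probe sets (617 at an unadjusted p under 0.05) and the 142 had been chosen on these same arrays.

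The adult arrays with bare names, wild-type 3 and mutant 1, lay closer to the larvae than the other adult arrays did, with mean correlations across probe sets of 0.903 and 0.891 against 0.830 to 0.837. In the RMA values no compressed range was seen over 3044 probe sets unchanged with stage. Their SD was 1.039 and 1.054 times that of the other adult arrays, which ranged from 0.984 to 1.017. RMA had already made the arrays' values comparable, so this check cannot exclude a compressed range before that step. More degraded RNA remained a candidate explanation, with 3' to 5' log2 differences of control probe sets of 1.163 and 1.32 against 0.818 to 0.960 on the other adult arrays. Larval arrays had means of 0.933 to 1.175, so this measure may in part also restate closeness to the larvae. Ubiquitin gave 3.24 and 3.38 against 2.67 to 2.92 on the other adult arrays and 3.28 to 3.52 in larvae. Actin, at 0.25 and 0.61, lay above all other arrays, while Gapdh on mutant 1 (−0.030) did not exceed adult mutant 2 (−0.006). Animals less advanced from larva to adult were neither supported nor excluded, since positions between the larval and adult levels of at most 0.6858, against 0.912 to 1.09 on the other adult arrays, restate that these arrays lie closer to the larvae. That explanation stayed open, and no genotype explanation was tested since the pair holds both genotypes.

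In adults, 10 of the 10 splits of the 6 arrays gave as many called probe sets as the real split (0, with 0 as the highest of the others), which a real count of 0 makes certain, and so few splits cannot give a share under 0.05 in any case. At an unadjusted p under 0.05, the real split gave 69 and another split, with wild-type 1, wild-type 2 and mutant 3 together, gave 3779, which points to a structure of the arrays other than genotype. For stage, 1 of the 100 splits within genotype, the real one, reached 8033 calls, but 10 of these splits keep the correlated array pairs whole, and so few cannot give a share under 0.05. The highest of the others, 6675, was among those 10 and set the 4 adult arrays with letter names against the larvae and the adult arrays with bare names, and the fit with array pairs as a random block gave 5169 calls.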

How the results depend on the processing

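The letter pairs as a block, fixed or random, the fits without the adult arrays with bare names, and an estimated correlation in these or with the naming block were added only after the data had been seen. The counts of 0 probe sets in limma for the larval, adult and interaction comparisons held under each of 23, 23 and 20 alternatives, with up to 799, 623 and 532 at an unadjusted p under 0.05. With the replicate numbers of the titles as a block, which pair no adult arrays, they were 0 in limma, with 76 in adults and 91 for the interaction at an unadjusted p under 0.05, and stage gave 6089. nep-1 kept its direction in 22 alternatives per stage, from −4.14 to −3.16 in larvae and from −1.90 to −1.16 in adults. The stage count ran from 4390 (log2 change of at least 1, which by construction drops smaller changes) to 11653, with 5169 for the random block, and from 5358 to 10409 when leaving out each array, where a lone array was assumed to vary like the other groups. Called larval lists, 4 as reported, numbered 1 with an estimated correlation and 0 with fry, but 5 with the naming block and 6 with the letter block, array weights, centring, the stage alone, scaled signals or without the adult arrays with bare names, and 0 to 6 when leaving out each array. With an estimated correlation the naming block gave 1, the letter block 0 and the fit without the bare names 0. Nearly all list members had been chosen by the study on the larval arrays, so these larval counts are no independent evidence of a change. Called adult lists, 0 as reported, numbered 2 with the letter block, 1 with the naming block, 1 with scaled signals, 2 without the arrays with bare names, but 0 in each of the fits with an estimated correlation, and 0 to 4 when leaving out each array. Medians of adult lists, here over probe sets, changed sign. The collagens gave 0.093 with array weights, 0.65 without the arrays with bare names and −0.88 to 0.57 when leaving out each array. The glutathione S-transferases gave 0.023 with array weights, 0.078 with scaled signals, 0.10 without the bare names and −0.20 to 0.069. The hedgehog-related list gave 0.24 without the bare names and −0.76 to 0.91, the lipid list −0.51 to 0.10, and abu and pqn −0.61 to 1.68. In larvae col-77 ranged from −3.15 to 0.042 when leaving out each array, positive without larval wild-type 2. For the random block and for these lists and gene the cause was not tested. Stage differences of named genes kept their direction and call 224 times and lost the call 16 times, most of them for dpy-5. The arrays' signal over background limits what can be seen of probe sets called absent.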

Other observations

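The tests of each stage's lists in the other stage, with and without nep-1 and 173014_at, and the choice of 173014_at were made only after the values were seen. Probe sets chosen by the authors' calls in larvae were tested on the adult arrays with camera, and the reverse, as 5 tests. The 12 probe sets decreased in 4 of 4 larval pairs, nep-1 and 173014_at among them, had a median adult log2 difference of −0.25 with 11 of 12 lower (camera adjusted p = 0.000247, or p = 0.0645 with an estimated correlation and p = 0.183 without the adult arrays with bare names). Without those 2 probe sets the median was −0.19 with 9 of 10 lower (adjusted p = 0.0774), so the test did not pass. The 44 probe sets increased in larvae had a median of 0.17 in adults with 32 of 44 higher (camera adjusted p = 0.00425, or p = 0.194 with an estimated correlation, p = 3.1e-05 with the letter pairs as a block and p = 0.00190 without the bare names). Within the adult pairs their medians were 0.25 (letter A), −0.09 (letter B) and 0.38 (bare names), so the pairs differed in direction. In the other direction, 40 probe sets decreased in at least 6 of 9 adult pairs passed the filter on present calls, of 47 before it. These 40, which hold the same 2, had a median of −0.14 in larvae with 28 of 40 lower (camera adjusted p = 0.00111, or p = 0.339 with an estimated correlation). Without those 2 the median was −0.06 with 26 of 38 lower (camera adjusted p = 0.0774, or p = 0.588 with an estimated correlation). The 44 probe sets increased in at least 6 of 9 adult pairs had a larval median of −0.07 (camera adjusted p = 0.909).

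The probe set 173014_at, which has no gene number in the authors' lists, followed nep-1 across the arrays. In larvae it measured 7.62 and 8.97 in wild-type and 3.95 and 4.01 in the mutant, where it was called absent on both arrays. The wild-type mean was 19.9-fold higher (limma adjusted p = 1), or 12.5-fold higher without larval wild-type 2. These are estimates from few arrays, not lower limits. In adults the difference was −1.61 ± 0.53 (3 arrays per genotype, limma adjusted p = 1), and it was lower in the mutant in each of the 5 array pairs, with differences of −3.68 and −4.96 in larvae, limited by background, and −0.96, −1.58 and −2.30 in adults. Its sequence was not analysed here.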
